A study of Mus musculus with 12 samples.

How the data were processed

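The series holds 12 libraries in 4 groups of 3, assigned from the treatment and assay in the sample labels: RNA and ATAC libraries of lumbar dorsal root ganglia under MS275 or vehicle after dorsal column axotomy. Per the labels' protocols, RNA with an integrity number above 8 was selected for poly(A), made into strand-specific libraries and sequenced in pairs of 75 bp on a HiSeq4000; ATAC used 50000 nuclei per reaction and 11 PCR cycles. The replicate numbers are those of the sample titles, and the series' design text describes the triplicates as biological.

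The deposited RNA files hold whole-number read counts per gene symbol, raw and not normalised. Per the submitters' processing notes the build was mm10 and the tools included STAR 2.7.0, edgeR 3.24.3, limma 3.38.3, R 3.5.0 and FastQC 0.10.1, with no role or order. The files set 0.59% to 0.63% of a library's reads aside in a row named ambiguous. The counter and its strand setting are not given in the sources used here. How reads of overlapping or antisense genes were otherwise assigned is therefore not known. The 5 rows of each file that name no gene, holding 18.89% to 20.56% of a library's reads, stayed out of library sizes and tests. The deposited ATAC files are peak lists of combined replicates, 1 per treatment, with columns that hold, per the file's layout and values, a score, a fold enrichment ratio, a summit offset and the -log10 of a p-value and of a q-value, all deposited by the authors' caller, whose name is not given in the sources used here. Fold and p are the authors' values and were used only to rank, filter or describe regions within a list.

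RNA counts were fitted with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, quasi-likelihood test, 2-sided, Benjamini-Hochberg adjusted p under 0.05), with treatment as the only term and 16819 of 44345 genes tested; CPM are counts scaled by the normalised library sizes, and standard errors are the log2 fold change divided by the square root of the quasi-likelihood F. The biological coefficient of variation was 8.62%. Gene lists, 37 of them fixed before the data were examined, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, and an estimated correlation beside it) and with fry, which tests whether the genes of a list move one way on balance and does not compare the list with other genes. With the estimated correlation camera called 0 lists, and 1 had an unadjusted p under 0.05. The first component of the log2 CPM held 46.6% of the variance. On it the vehicle libraries lay from -23.26 to -14.48, and MS275 replicates 1, 2 and 3 at 40.25, 4.66 and 14.13. No pair of libraries within a group agreed within sampling noise. The chi-square per degree of freedom was 6.78 to 8.26 between vehicle libraries and 17.3 to 49.5 between MS275 libraries, which differed more from one another. On simulated data with known answers for this comparison (16819 genes, 200 changed), 76.1% of genes changed 1.5-fold, 91.0% at 2-fold and 97.0% at 3-fold were recovered, and 7.4% of calls were false. The simulation drew each gene independently and changed genes by 1.5-fold or more. Most changes in the data were smaller and some genes varied together, so these rates may not carry over.

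Named genes followed a rule fixed before the data were examined: adjusted p under 0.05, mean log2 CPM of at least 1, no overlap between the groups' libraries, the 12 largest changes per direction, passing over provisional symbols, with up to 4 members of smallest p per list, and Hdac1, Hdac2 and Hdac3; some genes that this rule takes are not reported here. Gene coordinates came from a RefSeq table of the GRCm38.p6 assembly, the assembly of mm10, which matched 15985 of the tested genes (95%), 1049 of them through synonyms. That table has no strand, so the planned window around transcription starts became 1000 bp around either end of a gene, and the planned search for sequence motifs, which needs a genome, was not run.

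Overlapping ATAC entries were merged within each list and compared with bedtools 2.31.1, with an overlap of at least 1 bp. Alternatives covered the normalisation, the filter, the replicate number as a block, each library left out, mitochondrial and haemoglobin genes left out, DESeq2 1.42.0, limma voom, other thresholds, and for ATAC a -log10 q of at least 5, the overlap rule, equal list sizes and windows of 500 and 2500 bp. A muscle covariate and an estimated correlation in each alternative fit were added after the data were seen. Depth sets the precision of both assays: RNA libraries held 34992533 to 60370523 assigned reads, and the depth of the ATAC libraries is unknown here.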

Results

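RNA and open chromatin were measured in lumbar (L4 to L6) dorsal root ganglia of C57BL/6 mice aged 6 to 8 weeks, 24 h after the dorsal columns of the spinal cord had been cut. These ganglia hold the cell bodies of sensory neurons whose central axons run in the dorsal columns, together with satellite glia, Schwann cells, vessels and resident immune cells. Mice received MS275 (entinostat, an inhibitor of class I histone deacetylases) at 12 mg/kg or its vehicle, at the time of injury and again 2 h before the tissue was taken. RNA sequencing covered 3 MS275 and 3 vehicle libraries, each a pool of 2 mice. Reads assigned to genes numbered 45077599, 60370523 and 39148369 in vehicle replicates 1, 2 and 3, and 47750643, 56542966 and 34992533 in MS275 replicates 1, 2 and 3. ATAC-seq, which maps DNA open to a transposase, covered 3 mice per treatment, for which 1 pooled peak list per treatment was analysed.

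The RNA comparison asked which transcripts differed in injured ganglia between mice given MS275 and mice given vehicle. Transcripts that fell with MS275 included several that encode regulators of chromatin. Sirt1, an NAD-dependent deacetylase, went from 11.7 ± 0.37 CPM in vehicle to 5.68 ± 0.45 CPM with MS275 (SD, n = 3), a log2 fold change of -1.04 (SE 0.09). Suv420h1, a methyltransferase for histone H4 lysine 20, went from 34.7 ± 1.35 to 18.8 ± 0.37 CPM (log2 fold change -0.88, SE 0.06). Transcripts that rose included Calcb, which encodes the neuropeptide CGRP-beta (128 ± 4.48 to 202 ± 7.33 CPM, log2 fold change 0.66, SE 0.05), and Rara, which encodes retinoic acid receptor alpha (7.11 ± 0.62 to 15.3 ± 1.36 CPM, log2 fold change 1.10, SE 0.10). Of 16819 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 858 rose and 991 fell, most of them by small factors: 282 rose and 135 fell by 1.5-fold or more.

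The 12 genes that fell most by the fixed rule were Sirt1, Slx4, Zfp273, Fadd, Ing5, Suv420h1, Zfp472, Mier3, Zfp568, Slitrk2, Pdik1l and Zfp235, with log2 fold changes from -1.04 to -0.84. Ing5 is a subunit of histone acetyltransferase complexes (-0.90, SE 0.10), Slx4 a scaffold for DNA repair nucleases (-1.0, SE 0.10), and Fadd an adaptor of death receptors (-0.90, SE 0.15). Zfp symbols denote zinc finger proteins, of which Zfp273 fell from 4.64 ± 0.27 to 2.32 ± 0.13 CPM. In mm10, Sirt1 lies on chromosome 10 from 63319005 to 63339035 and Suv420h1 on chromosome 19 from 3767362 to 3818303. Suv420h1 overlaps Gm16066 there, and how reads of the overlap were assigned is not known. Each of the 12 still fell when MS275 replicate 1 was left out. They were chosen in a fit that held the same libraries, so that is no independent check.

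The 12 genes that rose most by the same rule were all transcripts of striated muscle: Atp2a1, Myh4, Tnnt3, Tnni2, Acta1, Ckm, Tnnc2, Myl1, Mylpf, Ttn, Actn3 and Mybpc2. Acta1, skeletal muscle actin, went from 5.10 ± 5.14 to 53.7 ± 56.5 CPM (log2 fold change 3.48, SE 0.83). MS275 replicate 1 carried most of this signal. The summed level of 9 muscle genes, the fixed list without Pvalb, was 15.4, 7.9 and 60 CPM in the vehicle libraries and 688.1, 88.0 and 97.5 CPM in the MS275 libraries. Without MS275 replicate 1, 5 of these 12 genes passed and 7 did not (Atp2a1, Myh4, Tnnt3, Ckm, Tnnc2, Myl1 and Ttn). Because this group filled the rule, the 12 higher genes of smallest p under the same conditions were taken in addition, after the data were seen; they included Calcb, Ly86, Ier3, Ehbp1l1, Rara, Ier5, Il25, Fstl3, Acbd4, Bhlha9 and Rhoc. Il25, an IL-17 family cytokine, went from 1.09 ± 0.19 to 4.10 ± 0.40 CPM (log2 fold change 1.90, SE 0.17). Fstl3, a secreted activin-binding protein, had a log2 fold change of 1.06 (SE 0.10), the early response genes Ier3 and Ier5 0.73 and 1.06, and the GTPase gene Rhoc 0.46. All 12 passed without MS275 replicate 1, but they were chosen by p in a fit that held the same libraries. Their passing is therefore no independent check. Ehbp1l1, Rara, Fstl3 and Acbd4 overlap other annotated genes, as do Atp2a1, Tnnt3, Ckm, Mylpf, Mybpc2 and Zfp273, and their counts are uncertain to that extent.

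**Figure D1:**
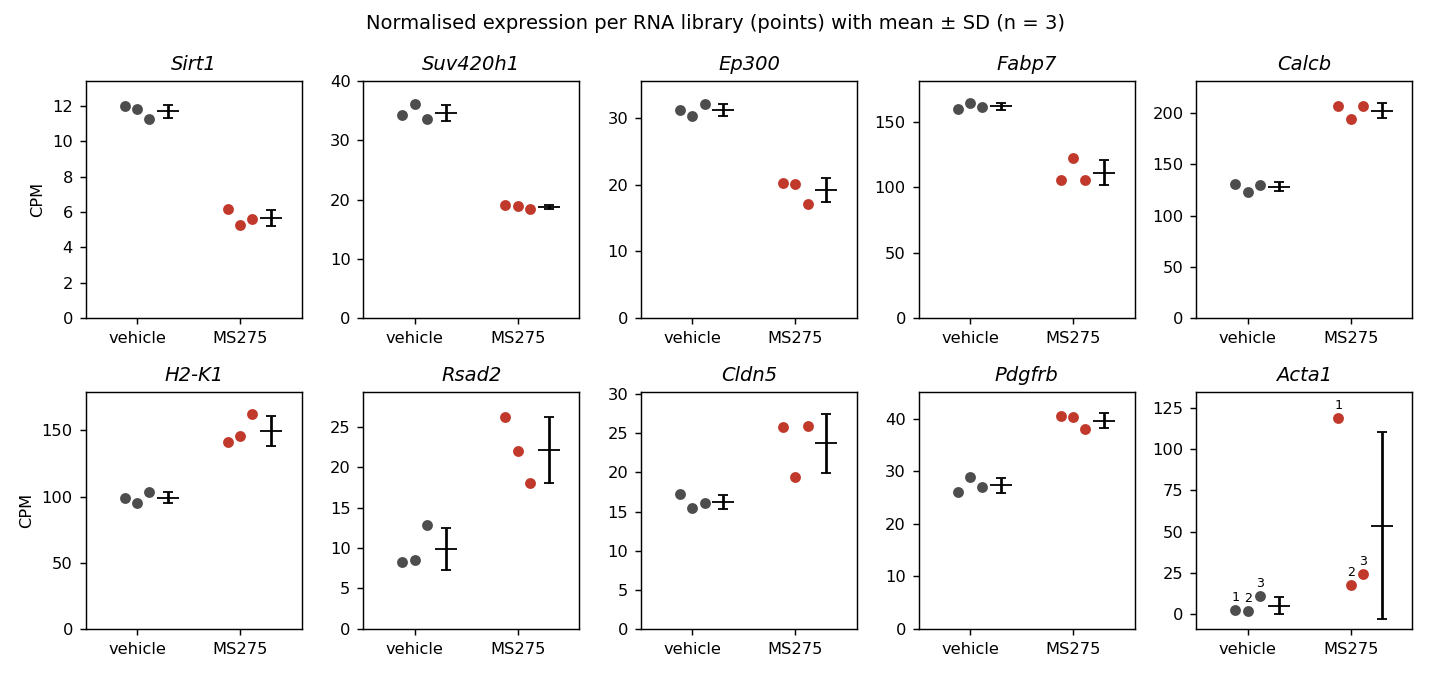
Each panel plots the normalised expression of 1 gene in CPM, with a point for each of the 3 vehicle and 3 MS275 libraries and the mean and SD beside them. Sirt1, Suv420h1, Ep300 and Fabp7 were lower in every MS275 library than in every vehicle library, Calcb, H2-K1, Rsad2, Cldn5 and Pdgfrb were higher, and the points of Acta1 carry their replicate numbers because MS275 replicate 1 stood far above the rest.

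Transcripts of the drug's targets stayed near their vehicle level: Hdac1, Hdac2 and Hdac3 had log2 fold changes of 0.02 (SE 0.06), 0.04 (SE 0.04) and 0.02 (SE 0.05), with adjusted p of 0.84, 0.49 and 0.83 in edgeR's quasi-likelihood test. Among 20 class I deacetylases and co-repressors, 2 rose (Mta1, 0.20, and Hdac8, 0.30) and 1 fell (the scaffold gene Sin3a, -0.48); adjusted over the list alone, 2 rose and 3 fell. The median of this list was 0.014, its mean -0.013, and camera's direction lower (adjusted p = 0.847). Of 14 other deacetylases, Sirt4 rose (0.44) and Sirt1 fell; adjusted over the list alone, 2 rose and 1 fell. Of 12 histone acetyltransferase genes, 4 fell and 0 rose. Those that fell were Ep300 (-0.70, SE 0.07) and Crebbp (-0.51, SE 0.08), the paired coactivators p300 and CBP, and Kat6b (-0.41) and Kat6a (-0.42). Adjusted over the list alone, 5 fell, and over all genes 2 fell when vehicle replicate 1 was left out. Camera placed this list lower (adjusted p = 0.00859), with adjusted p = 0.738 with an estimated correlation and adjusted p = 0.0457 in fry; with the muscle covariate camera gave adjusted p = 0.0993. Of 18 histone genes, 2 rose, both encoding replication-independent histones (H3f3b, 0.35, and H1f0, 0.40), the same count as adjusted over the list alone; the list's median was -0.06, its mean 0.004, and camera's direction higher (adjusted p = 0.847).

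Among the neuronal lists, that of nociceptor transcripts had the highest number of members that passed, though most of its members did not. Of 22 genes, 7 rose and 0 fell, and 10 rose adjusted over the list alone. Besides Calcb they included Mrgprx1, an itch receptor gene (0.74, SE 0.10), and Tac1, the substance P precursor (0.38, SE 0.08). Camera placed the list higher (adjusted p = 0.00798), with adjusted p = 0.738 with an estimated correlation, adjusted p = 0.0457 in fry, and adjusted p = 0.0509 without MS275 replicate 2. Of 18 pan-sensory neuron genes only Elavl4 rose (0.19, SE 0.04), or 3 adjusted over the list alone; camera gave adjusted p = 0.0103, and adjusted p = 0.81 with an estimated correlation. Of 16 genes of large-diameter neurons, Pvalb (0.28), which muscle also expresses, and Calb1 (0.26) rose, also 2 adjusted over the list alone; camera gave adjusted p = 0.233, and with the muscle covariate it placed the list higher (adjusted p = 0.0186, and adjusted p = 0.755 with an estimated correlation in that fit; median 0.054 before and 0.153 after). Of 25 neuronal ion channel genes, Kcna4 rose (0.27) and 3 fell, Kcnk18 (the TRESK potassium channel, -0.71, SE 0.11), Cacna1b (-0.27) and Cacna1c (-0.25). Adjusted over the list alone, 1 rose and 4 fell, and over all genes 0 rose and 1 fell when vehicle replicate 1 was left out. Of 22 presynaptic vesicle genes, Sv2a (0.22) and Syt7 (0.21) rose, also 2 adjusted over the list alone; camera gave adjusted p = 0.103, and placed the list higher with the muscle covariate (adjusted p = 0.0177) and without MS275 replicate 1 (adjusted p = 0.0274). With an estimated correlation these fits gave adjusted p of 0.755 and 0.636.

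Of 26 regeneration-associated genes, Klf6 (0.25, SE 0.05) and Nts (0.72, SE 0.20) rose and Arg1 (-0.84, SE 0.23) fell, and adjusted over the list alone 4 rose and 1 fell. The list's median was 0.076 (camera adjusted p = 0.253), and with the muscle covariate it was 0.193, where camera at the preset correlation placed it higher (adjusted p = 0.0186, and adjusted p = 0.755 with an estimated correlation in that fit). Of 20 growth factor and receptor genes, Gfra2 rose (0.24), also 1 adjusted over the list alone. Over all genes, 2 of 24 rose and 1 fell with no filter beyond 1 count, and 0 of 22 passed without vehicle replicate 1. Of 23 growth inhibitors and their receptors, Sema3f rose (0.29) and Neo1 fell (-0.20), and 0 passed adjusted over the list alone.

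Satellite glial markers split. Of 16 genes, 3 rose and 4 fell (3 and 6 adjusted over the list alone): glutamine synthetase, Glul (0.29, SE 0.04), was among those that rose, while Fabp7 fell from 162 ± 2.49 to 111 ± 9.53 CPM (-0.54, SE 0.06) and Ttyh1 fell (-0.34). None of 18 myelinating Schwann cell genes passed in edgeR, over all genes or adjusted over the list alone; 2 had an unadjusted p under 0.05, and DESeq2 called 1 and limma voom 0.

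The vascular genes that passed all rose. Of 16 endothelial genes, 6 rose and 0 fell, with Ly6c1 (0.46), Cldn5 (0.54, SE 0.11), Robo4 (0.54) and Egfl7 (0.47) among them, and 8 rose adjusted over the list alone (camera adjusted p = 0.000163, and adjusted p = 0.738 with an estimated correlation). Of 10 mural cell genes, 4 rose, 5 adjusted over the list alone: Pdgfrb (27.3 ± 1.5 to 39.6 ± 1.41 CPM, 0.54), Cspg4 (0.58), Rgs5 (0.33) and Des, which striated muscle also expresses (2.19). Camera gave adjusted p = 0.00535 for mural genes, adjusted p = 0.748 with an estimated correlation and adjusted p = 0.764 with the muscle covariate. Of 14 fibroblast genes, Lum rose (0.25), also 1 adjusted over the list alone. In the same libraries the summed muscle level was 88.0 to 688.1 CPM with MS275 against 7.9 to 60 CPM in vehicle.

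The immune recognition genes that passed all rose. Of 14 antigen presentation genes, 7 rose, the same count as adjusted over the list alone, with H2-K1 (99.0 ± 4.13 to 150 ± 11.3 CPM, 0.60), B2m (0.49), H2-D1 (0.43) and H2-Eb1 (0.49) as the members of smallest p; H2 genes resemble one another, so their counts are uncertain to that extent. Camera gave adjusted p = 0.00079, and adjusted p = 0.738 with an estimated correlation. Of 22 interferon response genes, 5 rose, and 9 adjusted over the list alone, among them the antiviral genes Rsad2 (1.17, SE 0.18), Isg15 (0.96, SE 0.22), Ifit3 (0.83) and Bst2 (0.58). Camera gave adjusted p = 0.000163, and adjusted p = 0.819 with an estimated correlation. Of 15 cytokine and chemokine genes, Il1b (1.07) and Ccl5 (1.54) rose, both below 1 CPM, and 4 rose adjusted over the list alone (camera adjusted p = 0.178). With no filter beyond 1 count 5 of 20 rose, with a median of 0.632 against 0.33 (camera adjusted p = 0.0362, and adjusted p = 0.688 with an estimated correlation). None of 19 macrophage, 12 neutrophil or 9 lymphocyte genes passed in edgeR, over all genes or adjusted over each list alone; 2, 4 and 0 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0. The neutrophil genes depended on the libraries used: without MS275 replicate 2, 12 of 13 rose (camera adjusted p = 0.00106), and without MS275 replicate 1, 0 rose and the median log2 fold change was 0.049 (camera adjusted p = 0.629). With no filter beyond 1 count 8 of 14 rose (camera adjusted p = 0.0329), and camera gave adjusted p = 0.037 without vehicle replicate 1. With an estimated correlation, adjusted p was 0.745 without MS275 replicate 2, 0.851 with no filter and 0.787 without vehicle replicate 1. With all libraries the neutrophil median was 1.05, and the summed neutrophil level was 84.1, 76.4 and 52.2 CPM in vehicle and 301.2, 55.3 and 91.5 CPM with MS275.

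**Figure D2:**
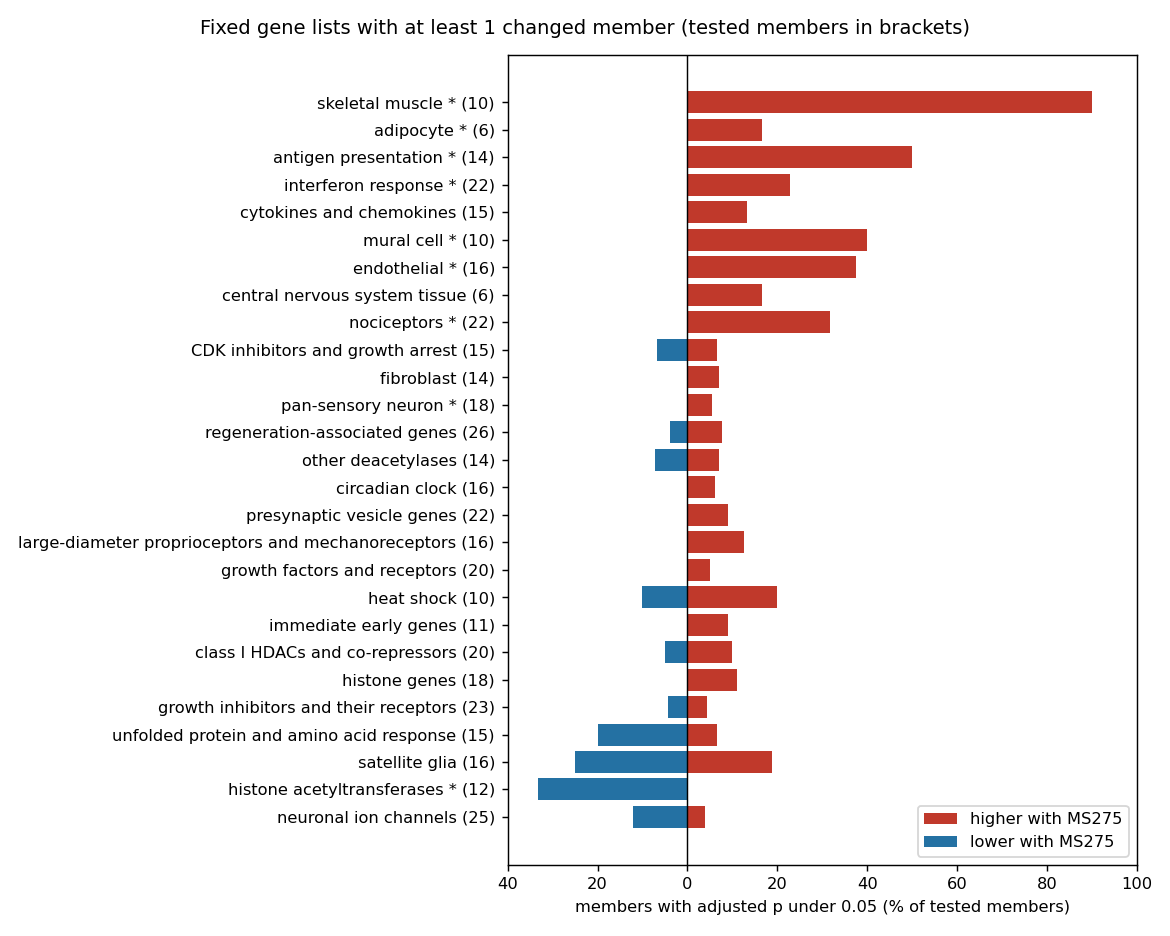
Bars give the percentage of the tested members of each fixed gene list that rose (right) or fell (left) with MS275 at an adjusted p under 0.05, for the 27 lists with a changed member, ordered by median log2 fold change. An asterisk marks an adjusted p under 0.05 in camera with the preset correlation, which none of them kept with an estimated correlation, and the skeletal muscle list stands out with 9 of 10 members higher.

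Of 10 skeletal muscle genes, 9 rose, and 10 adjusted over the list alone; camera gave adjusted p = 0.00039, and adjusted p = 0.81 with an estimated correlation. The member that did not pass was Myh1 (3.57, adjusted p = 0.0881 over all genes), and the 9 genes became 0, 0 and 4 without vehicle replicate 1, 2 or 3, 4, 10 and 4 without MS275 replicate 1, 2 or 3, and 1 with limma voom. Of 6 adipocyte genes, Cfd rose (0.88), also 1 adjusted over the list alone, with camera adjusted p = 0.0374 and adjusted p = 0.81 with an estimated correlation; camera gave adjusted p of 0.0522, 0.133 and 0.0615 without vehicle replicate 2, MS275 replicate 1 and MS275 replicate 3. With the muscle covariate the adipocyte median went from 0.865 to 0.151 (camera adjusted p = 0.712), and that of the muscle genes, from which the covariate was built, from 3.46 to 0.191 (camera adjusted p = 0.309). None of 7 erythroid genes passed in edgeR, over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0. Haemoglobin reached 414.1 CPM in MS275 replicate 1 against 89.7 to 205.5 CPM in the other libraries. Of 6 central nervous system genes, Aqp4 rose (0.50), also 1 adjusted over the list alone.

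The growth arrest, heat shock and unfolded protein lists gave calls in both directions. Of 15 CDK inhibitor and growth arrest genes, Cdkn1a (p21, 0.39, SE 0.07) rose and Ccng2 (-0.39, SE 0.07) fell, the same counts as adjusted over the list alone. Of 10 heat shock genes, Hspa1a (0.74) and Bag3 (0.17) rose and Dnajb1 (-0.21) fell, again as over the list alone; camera gave adjusted p = 0.233, and with the muscle covariate it placed the list higher (adjusted p = 0.0177, and adjusted p = 0.755 with an estimated correlation in that fit; median 0.049 before and 0.112 after). Of 15 genes of the unfolded protein and amino acid response, Atf4 rose (0.21), while the serine synthesis genes Phgdh (-0.37) and Psat1 (-0.22) and the kinase-like gene Trib3 (-0.56) fell; adjusted over the list alone, 1 rose and 4 fell. Of 11 immediate early genes Ier3 rose, also 1 adjusted over the list alone. None of 29 proliferation, 20 cholesterol synthesis, 15 glucocorticoid response, 7 mitochondrially encoded or 4 sex-linked genes passed in edgeR, over all genes or adjusted over each list alone. Of these, 2, 5, 5, 1 and 0 had an unadjusted p under 0.05, DESeq2 called 1, 1, 2, 1 and 0, and limma voom 0. The glucocorticoid genes depended on the setting: 4 rose and 1 fell with no filter beyond 1 count, 4 rose without MS275 replicate 2, and 1 rose and 2 fell without MS275 replicate 1. Of the cholesterol genes, 1 fell with no filter or without MS275 replicate 1, 2 fell without MS275 replicate 2 and 1 rose without MS275 replicate 3. The proliferation median was 0.019 while camera's direction was lower (adjusted p = 0.381); the median turned to -0.28 without MS275 replicate 1 (camera adjusted p = 0.00334) and to -0.33 with the muscle covariate (camera adjusted p = 0.0177). With an estimated correlation these fits gave adjusted p of 0.636 and 0.755.

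The 1849 changed genes became 375, 261 and 728 without vehicle replicate 1, 2 or 3, and 1875, 2763 and 882 without MS275 replicate 1, 2 or 3. Without MS275 replicate 1, the library with most muscle signal, 699 of the 858 higher and 782 of the 991 lower genes were called again. With the muscle signal as a covariate, an alternative added after the data were seen, 41 genes were higher and 17 lower. Of 99 named genes that passed, 55, 59 and 37 did not pass without vehicle replicate 1, 2 or 3, 16, 6 and 35 without MS275 replicate 1, 2 or 3 (Hdac8, Neo1, Cfd, Il1b, Ccl5, Dnajb1, Cacna1c, Arg1, Trib3 and the 7 muscle genes above without replicate 1), and 78 with the covariate. The endothelial, interferon, antigen presentation, mural and nociceptor genes that rose numbered 0, 1, 1, 2 and 3 without vehicle replicate 1, 1, 1, 1, 1 and 2 without vehicle replicate 2, 2, 7, 3, 3 and 3 without vehicle replicate 3, and 1, 2, 3, 3 and 6 without MS275 replicate 3.

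The ATAC comparison asked where open chromatin differed between the treatments, and with 1 pooled list per treatment it has no replicate error. Merged regions numbered 177906 in the vehicle list and 161788 in the MS275 list, covering 92.19 and 80.07 Mb. Of the vehicle regions 47.5% overlapped an MS275 region by at least 1 bp, and of the MS275 regions 52.8% overlapped a vehicle region. When each list was ranked by p into 10 equal parts, 98.6% of vehicle and 99.3% of MS275 regions were shared in the part of smallest p, and 24.2% and 28.4% in the last. Width fell along the same ranks, from a median of 973 to 352 bp in vehicle and from 950 to 341 bp with MS275, and wider regions meet a rule of 1 bp more easily, so strength and width were not separated. Regions within 1000 bp of either end of a protein-coding gene made up 12.5% (95% interval 12.4 to 12.7) of the vehicle list and 12.7% (12.5 to 12.8) of the MS275 list, by exact binomial intervals that cover counting error only. They made up 19.8% of shared regions in either list, against 5.93% of regions found in the vehicle list alone and 4.65% of those in the MS275 list alone.

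**Figure D3:**
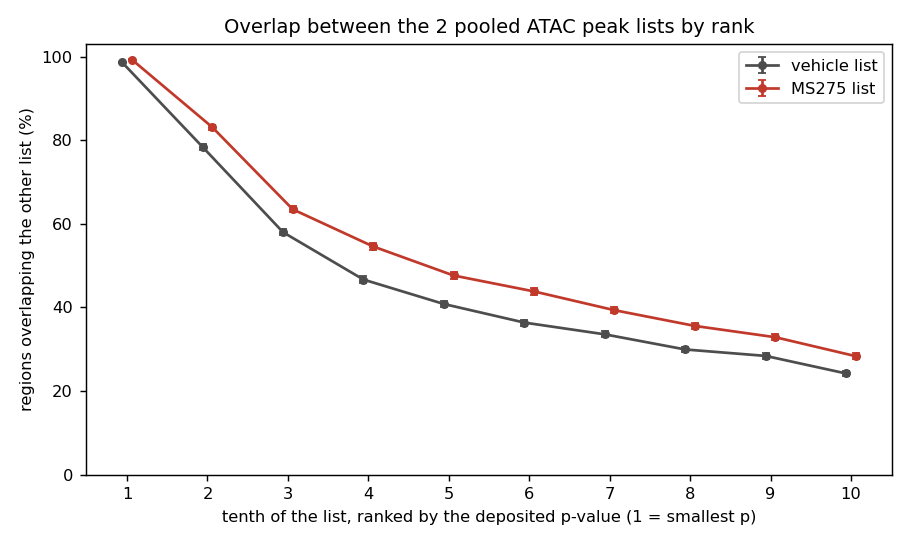
The share of regions that overlap the other list, in percent, is plotted for 10 equal parts of the vehicle and MS275 lists ranked by the deposited p-value, with exact 95% binomial intervals. Sharing runs from 98.6% and 99.3% in the first part to 24.2% and 28.4% in the last.

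The regions of highest fold found in the MS275 list alone lay on chromosome 9 from 15357176 to 15358369, overlapping Cep295, a centrosomal protein gene, and on chromosome 8 from 79294429 to 79295560, overlapping Mmaa, a gene of vitamin B12 metabolism. Their deposited fold enrichments were 8.45 and 8.37, and the third, on chromosome 12 from 39665525 to 39665750, outside protein-coding genes, had 3.30. The vehicle list as used here holds no region overlapping them; whether a filter or the entries used here account for that is not known, so presence in a single list does not show closed chromatin under the other treatment. The 3 of highest fold in the vehicle list alone lay on chromosome 11 from 43135454 to 43135795 within Atp10b (3.5), on chromosome 11 from 3127519 to 3127701, 4148 bp from Sfi1 (3.21), and on chromosome 18 from 14103252 to 14103436 (3.21). At the genes named above, both lists held a region over the high-coordinate end of Sirt1 (chromosome 10, 63338278 to 63339710 in vehicle and 63338234 to 63339645 with MS275) and over the low-coordinate end of Ep300 (chromosome 15, 81584915 to 81586805 and 81584912 to 81586522). Other named genes had an end region in a single list. Fstl3, Cdkn1a, Rgs5, Aqp4 and Ttn, which rose, and Arg1, which fell, had it in the MS275 list alone. Ttyh1 and Cacna1c, which fell, had it in the vehicle list alone. Among genes that the rule took but that did not pass, Hdac7 and Mfap5 had it in the MS275 list alone. Ccl7, Fcgr1, C1qa and Aif1, which did not pass either, had it in the vehicle list alone. Over all 840 genes that rose and had coordinates, 26 had an end region in the MS275 list alone and 23 in the vehicle list alone.

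Genes that fell with MS275 mostly had open ends in both lists. Of 975 such genes with coordinates, 93.5% had an end region in both lists, against 83.9% of the other 15007 genes (odds ratio 2.79, adjusted p = 5.05e-18, two-sided Fisher's exact test across genes, Benjamini-Hochberg over 6 tests). They less often had one in the MS275 list alone (0.51% against 2.22%, odds ratio 0.23, adjusted p = 9.32e-05) or in the vehicle list alone (1.33% against 3.67%, odds ratio 0.36, adjusted p = 9.32e-05). Of 840 genes that rose, 3.10% had an end region in the MS275 list alone, against 2.06% of the others, which did not pass (odds ratio 1.52, adjusted p = 0.0723), and with regions of -log10 q of at least 5 the odds ratio was 2.06 (adjusted p = 0.000588). At that q the genes that rose also more often had one in the vehicle list alone (odds ratio 1.71, adjusted p = 0.000104) and less often in both lists (0.65, adjusted p = 1.69e-08), and within 2500 bp the odds ratio for the MS275 list alone was 0.99 (adjusted p = 1.0). Genes are not independent replicates, and the test compares a pair of lists, not conditions. The classes of both lists, MS275 list alone and vehicle list alone exclude one another, so their tests are not separate results. Expression level was not matched between the genes compared, so a link of level with both measures stays open. Genes of chromosome X stayed in the test under every setting. Of its protein-coding genes 33.95% had an end region in the vehicle list and 35.71% in the MS275 list, against 62.66% to 83.12% and 60.05% to 80.06% on the autosomes.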

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

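The muscle covariate and an estimated correlation in the alternative fits were chosen only after the result was seen, and all other alternatives were fixed before the data were examined. No gene called in one direction was called in the other under any alternative of the RNA fit. Leaving out libraries moved the higher genes between 127 and 1388 and the lower genes between 134 and 1375, lists called higher ranged from 7 to 10 and lists called lower from 1 to 3; smaller groups lower power by construction, but not all of these counts fell. At an adjusted p under 0.10, 1525 genes were higher and 1704 lower, and with a fold of at least 1.5 the counts were 282 and 135. With an estimated correlation 0 lists were called higher and 0 lower by camera, and fry called 1 higher and 1 lower. Camera with an estimated correlation also called 0 in every alternative fit of the counts. In those fits 0 to 2 lists had an unadjusted p under 0.05, and the smallest adjusted p was 0.576.

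With the muscle covariate 41 genes were higher and 17 lower, and 2 lists lower. The median log2 fold change of the genes called higher went from 0.38 (median SE 0.078) to 0.32 (0.115), and of those called lower from -0.33 (0.068) to -0.29 (0.103), with 857 of 858 and 991 of 991 on the same side. The calls ended with smaller changes and larger errors together. The covariate correlated at 0.77 with treatment, so removal of a muscle signal and loss of treatment signal cannot be told apart. Des changed side with it (-0.065), as did the macrophage list (adjusted p = 0.0251), and regeneration-associated, large-diameter neuron, presynaptic and heat shock lists became called higher. Over the left-out libraries Slc4a1 ranged from -0.96 to 1.34, Alas2 from -0.71 to 0.83 and the erythroid list's adjusted p from 0.0211 to 0.929, each lowest without MS275 replicate 1, where all 3 were called lower. Camera's calls also appeared for proliferation and presynaptic genes without MS275 replicate 1, for ion channel, macrophage and neutrophil genes without MS275 replicate 2, for Schwann cell and neutrophil genes without vehicle replicate 1, and for immediate early genes without MS275 replicate 3. The cause was not tested.

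The replicate number as a block gave 981 higher and 1107 lower genes. Deviations of same-numbered libraries correlated at 0.019, 0.111 and -0.061, and those of other-numbered libraries at -0.149 to 0.113. With 3 libraries per group these values cannot show whether the numbers pair the libraries, and the labels do not say. With the block camera called the neutrophil list (adjusted p = 0.0202, 1 gene higher) and changed no other list's call, and 3 glucocorticoid genes were higher and 1 lower. Over 37 lists and 178 named genes, 474 of 516 and 2053 of 2470 alternative values kept direction and side of the threshold or stayed uncalled, with 22 and 25 of them uncalled on the other side of 0; 24 and 320 lost the call, and 16 and 94 gained it.

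For ATAC, a -log10 q of at least 5 left 45078 vehicle and 32235 MS275 regions, and unmerged entries numbered 277369 and 246602. The shared percentages of the vehicle and MS275 lists were 53.9 and 75.6 at that q, 49.8 and 50.6 with equal numbers of regions, 35.1 and 38.6 with a reciprocal overlap of 50%, and 43.2 and 48.9 by summit. Shares at gene ends were 28.5% and 36.2% at that q, 9.74% and 10% within 500 bp, and 18.5% and 18.3% within 2500 bp. For genes that rose, the odds ratio of an end region in the MS275 list alone was 2.06 at that q, 1.57 with equal numbers and 1.61 within 500 bp, each then past the threshold, but 0.99 within 2500 bp (adjusted p = 1.0); at that q the ratio turned to 1.71 for the vehicle list alone and to 0.65 for both lists. The cause was not tested. Motif shares were not run. ATAC depth is unknown, so the number of weak regions may reflect it.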

Other observations

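Gene families in the next paragraph and all tests of the muscle, zinc finger and ATAC patterns were chosen only after the result was seen; the counts over other splits of the libraries were planned.

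The families were picked after results from these same libraries had been seen. Camera's p-values here were adjusted over these families alone and take no account of that choice, so they are no independent support. Among genes with a Zfp symbol, lower values with MS275 outnumbered higher ones. Of 315 tested genes with a Zfp symbol, 75 fell and 6 rose, with a median log2 fold change of -0.22 (edgeR quasi-likelihood test; camera adjusted p = 1.85e-17, and adjusted p = 0.0136 with an estimated correlation). Zfp719 (-0.63), Zfp84 (-0.75) and Zfp646 (-0.62) were among those that fell. The 6 that rose were Zfp36 (0.99), Zfp750 (1.83), Zfp57 (0.74), Zfp217 (0.64), Zfp608 (0.62) and Zfp516 (0.21). Zfp36 encodes the mRNA-destabilising protein tristetraprolin and is no DNA-binding repressor. Of 26 genes with a Kdm or Setd symbol, families that include histone demethylases and methyltransferases, 10 fell and 0 rose (camera adjusted p = 3.89e-06, and adjusted p = 0.0525 with an estimated correlation). Of 23 genes with an H2 symbol, most of them histocompatibility genes, 13 rose and 0 fell, with a median of 0.55 (camera adjusted p = 2.78e-08, and adjusted p = 0.0525 with an estimated correlation). H2-K1, H2-D1, H2-Eb1, H2-Aa and H2-Ab1 among the 13 also belong to the antigen presentation list above, so the 2 results are not separate. Of 84 cytosolic ribosomal protein genes, 9 rose, one of them the muscle gene Rpl3l (2.62), and 80 had a positive log2 fold change; their median of 0.16 went to 0.09 without MS275 replicate 1, where 7 rose and 1 fell, and to -0.02 with the muscle covariate (camera adjusted p = 5.19e-09, and adjusted p = 0.355 with an estimated correlation). Of 45 Nduf genes of respiratory complex I, 2 rose; their median of 0.12 went to 0.07 without MS275 replicate 1, to 0.18 without MS275 replicate 2, and to 0.01 with the muscle covariate (camera adjusted p = 0.000242, and adjusted p = 0.355 with an estimated correlation). Medians kept their sign under the other size factors and without any single library, but the counts did not hold: without vehicle replicate 1, 2 or 3, or MS275 replicate 3, 24, 15, 37 and 42 Zfp genes fell, 2, 3, 5 and 5 Kdm or Setd genes fell, and 1, 1, 7 and 9 H2 genes rose. Over the left-out libraries the ribosomal protein genes that rose numbered 0 to 46 and the Nduf genes 0 to 20, each highest without MS275 replicate 2.

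Direction also went with gene span. With the genes in 5 equal groups by span, 240 rose and 82 fell in the shortest (median 3.7 kb), and 92 rose and 225 fell in the longest (132.6 kb), a relation across genes, which are not independent replicates.

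Skeletal muscle transcripts differed between libraries of one treatment. The summed level of the 9 muscle genes spanned 7.64-fold within vehicle and 7.82-fold within MS275, and those genes stood together in MS275 replicate 1 (median log2 ratio to the other MS275 libraries 2.90, SD 0.58). Muscle carried over at dissection may therefore account for part of the signal, as a hypothesis. A response of ganglion cells to MS275 stays open and cannot be told apart from it: the lowest MS275 library was 1.47 times the highest vehicle library, less than the span within either treatment. The exact permutation p of the summed level was 0.1, two-sided, the smallest that 3 against 3 allows.

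The zinc finger pattern was set against gene span and muscle. The median of 314 Zfp genes was -0.216 as fitted. It was -0.221 (95% bootstrap interval -0.253 to -0.193) after the trend on span and level was removed. The fitted trend on span and level therefore does not account for that median. Without MS275 replicate 1 the median was -0.209 (-0.244 to -0.170), and with the muscle covariate -0.189 (-0.212 to -0.160). The value without MS275 replicate 1 argues against muscle in that library as the source, but not against muscle in the other libraries. The covariate correlated at 0.77 with treatment, and with it 1 of the Zfp genes fell. These intervals resample genes, which are not independent replicates, and hold no error between libraries. A drug response is a hypothesis that remains, untested against other treatments, and reads shared between similar Zfp genes were not tested.

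The shortfall of MS275 regions was uneven along the genome. The ratio of MS275 to vehicle regions ran from 0.743 on chromosome 19 to 1.13 on chromosome 3, and across the 19 autosomes it fell with genes per Mb (Spearman -0.895, permutation p = 1e-05, the smallest 100000 permutations can give, adjusted 4e-05 over 4 tests; Pearson -0.756, permutation p = 0.00017, adjusted 0.00034; without chromosomes 7 and 11, -0.892 and -0.785). Among regions of -log10 q of at least 5 0 of 19 autosomes had more in the MS275 list, yet the ratios differed (chi-square 4.4 per degree of freedom, counting error only; Spearman -0.5 and Pearson -0.511, adjusted permutation p = 0.032 for each). A lower depth, a bias linked to gene density and a drug effect cannot be told apart with 1 pooled list per treatment.

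The 6 RNA libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1849 genes in edgeR's quasi-likelihood test and the highest other 0, with 4787 genes at an unadjusted p under 0.05 against at most 1113. With camera at the preset correlation the real split called 9 gene lists and the highest other 12, and 8 of the 10 splits, the real one included, called at least 9; for genes that count was 1 of 10.

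Chromosome X held 569 vehicle and 562 MS275 regions, or 0.59 and 0.58 per protein-coding gene, against 5.84 to 10.9 and 5.07 to 10.8 on the autosomes; whether a filter or the entries used here set this level is not known. These regions had a median -log10 q of 11.6 and 10.8. The transcript RP23-81C12.3 ranged from 1838.9 to 15426.4 CPM, the latter in MS275 replicate 2.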
